A study of Mus musculus with 6 samples.

How the data were processed

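RNA from cultured mouse sympathetic neurons was measured on 6 two-colour Agilent expression arrays, 3 from untreated control neurons and 3 from neurons given interferon-gamma at 500 U per ml for 24 h. Per the labels, neuron RNA was in the Cy5 channel of every array. The Cy3 channel held the same kind of reference throughout, RNA of untreated sympathetic cervical ganglia of postnatal day 5. Total RNA was extracted with Trizol, and 500 ng of each RNA was amplified and labelled with the Low Input Quick Amp kit, per the labels' protocols. Per the submitters' processing notes, the images were read with Agilent Feature Extraction, whose version is not given in the sources used here. Dyes were not swapped on any array, so a dye effect of a gene stays in each ratio. It can cancel only in the difference between the groups, and only where the arrays share 1 ratio scale. The 99 genes with control means above 1.5 shifted by a median of -1.04 on interferon-gamma arrays 1 and 3 and 0.05 on array 2. Cancelling may therefore be incomplete. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

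The authors deposited 1 log ratio per array feature, already centred within each array, and these ratios are the values used here. The log2 scale of the deposited values was inferred. Their range, -9.00 to 10.73, is beyond what a scanner can record on a log10 scale, and log2 is the usual choice otherwise. If they were natural logs, all folds would be larger than given. The direction was taken as neuron RNA over ganglion reference, from the dyes in the labels and the usual red over green convention. With the opposite direction, textbook targets of interferon-gamma such as Irf1, Tap1 and Psmb9 would all have fallen in treated neurons, so the rise of known targets was used to settle the sign and is not independent of it. The 6 array medians lay between 0 and 0.005, so the authors had centred each array. Genes were not centred across arrays. No value was missing, but 309 to 715 features per array held exactly 0, against a mean of 37.4 to 43.8 features at each neighbouring value. Some zeros may therefore stand for ratios that were not measured. As signal and background were not analysed here, a ratio near 0 can also come from a gene below background in both channels, and folds of dim genes can be understated. A filter on dim features or another background correction was not possible.

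The array held 45220 features. The platform annotation, which can be old, gave 1 gene for 33653 of them, several for 56 and none for 11511. Of the features with 1 gene, 33517 were matched by gene number to the RefSeq table of GRCm38.p6, which was used only to update symbols. The annotation does not name probes, so replicate spots of 1 probe could not be told from different probes. The value of a gene on an array was the mean over its features, which gave 19087 genes. Features with several genes or none, which include any control spots, were left out of all gene comparisons. Of the 15 genes named in advance, 4 are not analysed here.

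Interferon-gamma and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), with Benjamini-Hochberg adjustment over all 19087 genes and a threshold of 0.05. Errors of a difference are standard errors of this fit, and intervals are at 95%. In each of 20 simulated data sets of 19087 genes, 200 genes were changed by a known amount and a list of 20 more was raised by 0.5. The noise was drawn independently with each gene's spread as moderated by limma. The interferon-gamma test then called 58% of the genes changed by 1 on the log2 scale, 94.3% of those changed by 2 and 97.9% of those changed by 3, and 4.78% of its calls were unchanged genes. Real arrays share errors across genes, and the moderated spread is below the observed one for the noisiest genes, so these shares are optimistic.

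Before the data were examined, 27 gene lists with 504 entries were written from textbook knowledge, and 462 entries were measured. They cover the interferon response, apoptosis around the release of cytochrome c, sympathetic neuron identity, and markers of other cells a ganglion culture can hold. Each list was tested against all other genes with limma's camera at the preset inter-gene correlation of 0.01, adjusted over the 27 lists. Camera with a correlation estimated for each list and fry, which asks only whether a list's genes move one way on balance, were run beside it. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Cultured neurons were set against the ganglion reference without a test, as the mean and SD over the 3 control arrays, since the reference was measured in a single dye and its own spread is unknown.

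Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap. It adds, for each list, the 3 members past the threshold with the largest change, or the 2 with the smallest p where none passed, and the 15 genes chosen in advance. Other genes named in the text were chosen after their values were seen. The alternatives were the replicate number as a block, median centring, quantile normalization, features tested singly, 1 feature per gene with the largest interquartile range, 2 filters on spread (the lower 50% by SD over all arrays, or the top 10% by SD within groups, left out), a robust prior, array weights, a further 2-fold threshold, an adjusted p under 0.1, genes on more than 1 list left out of the list tests, and each array left out in turn. Treating values of exactly 0 as missing, with at least 2 values required per group, was added after the data were seen. For genes that passed without interferon-gamma array 2, the median shift on arrays 1 and 3 of the 200 genes nearest in control mean, with changed genes kept, was also added after the data were seen. This median was the same, 1.37, for Birc5, Txnip, Icam1 and Bub1, at control means from -2.44 to -3.25. At such low ratios the match is therefore loose, and it may understate the shift expected there.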

Results

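Gene expression was measured in cultured mouse sympathetic neurons, the neurons of the sympathetic ganglia that depend on nerve growth factor, with and without interferon-gamma, a cytokine of activated T cells and natural killer cells. The study's title concerns protection of these neurons by interferon-gamma from apoptosis at the step where cytochrome c leaves the mitochondria. Each group had 3 arrays, and each array gave the log2 ratio of neuron RNA over RNA of postnatal day 5 ganglia. Pearson's r between arrays, across genes that are not independent replicates, was 0.61 to 0.71 within the control group, 0.61 to 0.78 within the interferon-gamma group and 0.35 to 0.72 between the groups. The number of arrays limits the precision of every value below.

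The first comparison asked which genes differed between treated and control neurons. The response to interferon-gamma was almost one-sided, and 213 genes rose and 4 fell among 19087 (limma, adjusted p under 0.05), and the risen genes had a median fold of 4.88. The largest rise was that of Cxcl10, a chemokine that attracts T cells, by 7.61 ± 0.85 (SE, n = 3 per group) on the log2 scale, which is 195-fold with a 95% interval from 47.0 to 809 (adjusted p = 0.0105). Its ratio on interferon-gamma array 2 was -0.575, against 2.10 and 2.35 on interferon-gamma arrays 1 and 3. Gbp3, a guanylate-binding protein, rose 141-fold, Rtp4, an antiviral gene, rose 64.0-fold, and Batf2, a transcription factor of the interferon response, rose 54.6-fold (adjusted p = 2.79e-05). The other 6 of the 10 largest rises were Gbp11, Gbp6, Ifi47, Igtp, Ubd and Gbp4, at 37.1-fold to 55.0-fold. Of the risen genes, 62 rose 8-fold or more.

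The 4 genes that fell were Dkk2, a secreted regulator of Wnt signalling, Esm1, a secreted proteoglycan known from endothelial cells, Tafa2, a secreted chemokine-like protein of neurons, and Plec, a cytoskeletal linker. Dkk2 fell by 2.25 on the log2 scale (SE 0.29, adjusted p = 0.0200), from a mean ratio of 1.70 ± 0.52 (SD, n = 3) to -0.55 ± 0.30. Esm1 fell by 1.54 (SE 0.16), Tafa2 fell by 1.29 (SE 0.14) and Plec fell by 0.83 (SE 0.12). The 4 features of Plec ranged from -1.77 to -0.43, and Plec did not pass without the genes of low SD (limma, adjusted p = 0.219). In all 217 genes the values of the 3 treated arrays did not overlap those of the 3 control arrays, a separation that 13.7% of all genes showed and that chance gives for 10%. Of the 217 genes, 198 changed at least 2-fold, 195 of them upwards and 3 downwards. At an unadjusted p under 0.05, 1006 genes were higher and 512 lower. Among 81 changed genes with 2 or more features, 3 had a feature of the opposite sign and 15 a feature with under 50% of the gene's change.

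The count of 217 depended on single arrays. It was 136 without control array 1, 133 without control array 2, 134 without interferon-gamma array 1, 113 without interferon-gamma array 3 and 508 without interferon-gamma array 2. Without 1 array or another, 13 of the 36 named genes past the threshold no longer passed, namely Cxcl10, Gbp4, C1ra, C1s1, C2, Mlkl, Ido1, Wars, Zap70 and the 4 genes that fell, all with the direction kept. With quantile normalization, Dkk2, Esm1, Plec, Gbp4 and Zap70 did not pass.

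**Figure D1:**
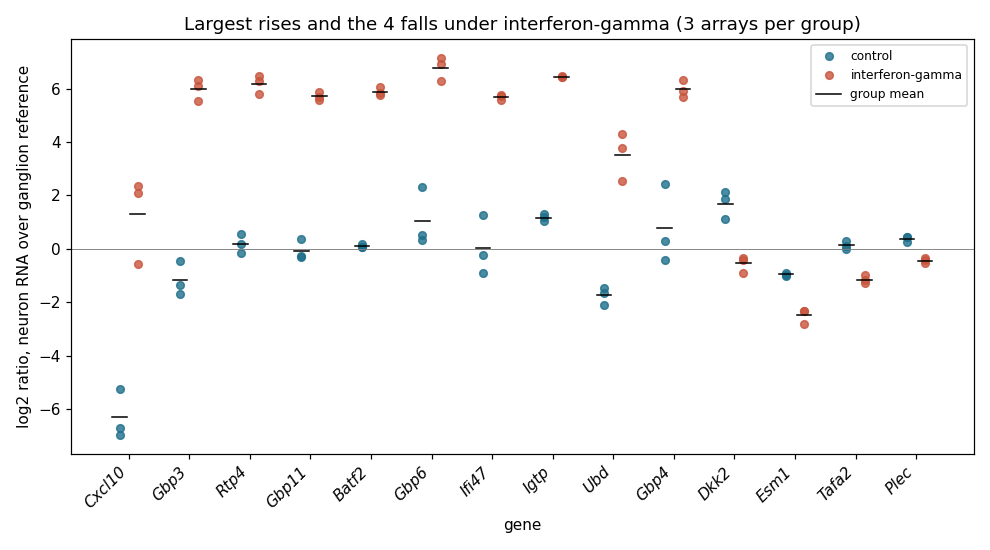
Log2 ratio of neuron RNA over the ganglion reference (vertical axis) for the 10 genes with the largest rises and the 4 genes that fell (horizontal axis). Points are single arrays, 3 per group, and black bars are group means; Cxcl10 moved from a mean of -6.31 to 1.29, while Dkk2 moved from 1.70 to -0.55.

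The list with the highest median was that of the guanylate-binding proteins and immunity-related GTPases, which defend cells against intracellular pathogens. Of 17 measured members, 15 rose (17 adjusted over the list alone), with a list median of 4.42 on the log2 scale (camera, adjusted p = 3.37e-49, and adjusted p = 0.040 with an estimated correlation). Gbp11 rose by 5.78 ± 0.21 (SE) and Gbp6 by 5.74 ± 0.55. The members that did not pass over all genes were Gbp5, at 2.37 ± 0.40, and Iigp1, at 7.47 ± 1.29, whose control arrays spread from 0.78 and 1.84 to 6.10. Control array 3 also had higher ratios than the other control arrays for Gbp6 (2.32) and Gbp4 (2.44). Some members of these families, and of the H2, Ifit, Oas and Apol families, are close to each other in sequence, so a feature of one can also bind RNA of another.

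In the list of interferon-gamma signalling, 7 of 18 measured genes rose (11 adjusted over the list alone; camera, adjusted p = 1.15e-14, and adjusted p = 0.040 with an estimated correlation). They were Irf1, Irf7, Irf8, Irf9, Batf2, Socs1 and Nmi. Irf8, a transcription factor, rose by 3.91 ± 0.14 (SE), Socs1, an inhibitor of Janus kinases, by 2.96 ± 0.19, and Irf1, an early target of the pathway, by 2.29 ± 0.17, although the 3 features of Irf1 ranged from 0.53 to 3.36. The receptor subunits did not pass the threshold. Their differences were -0.06 (95% interval -0.36 to 0.24) for Ifngr1 and -0.07 (-0.48 to 0.33) for Ifngr2.

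RNA of genes for antigen presentation by MHC class I rose broadly, with 21 of 26 measured genes past the threshold (22 adjusted over the list alone). The list median was 1.94 (camera, adjusted p = 1.70e-43, and adjusted p = 0.040 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, rose by 3.82 ± 0.15 (SE), the immunoproteasome subunit Psmb9 by 3.27 ± 0.16, and the class I gene H2-T10 by 3.27 ± 0.13. The class II list held 5 risen genes of 14 (8 adjusted over the list alone). Among them H2-DMb1 rose by 3.80 ± 0.29, H2-Aa by 2.94 ± 0.23 and Cd74, the invariant chain, by 2.92 ± 0.20. The class II medians were 1.37 and 1.29 on interferon-gamma arrays 1 and 3 and 0.45 on array 2, and macrophage markers, whose cells express class II, also had higher medians on arrays 1 and 3 (0.31 and 0.23) than on array 2 (-0.37). The class II list passed camera (adjusted p = 4.30e-11), and did not pass with an estimated correlation (adjusted p = 0.129 with an estimated correlation).

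Among antiviral genes that interferon-gamma shares with type I interferon, 30 of 35 rose (34 adjusted over the list alone), with a median of 2.26 (camera, adjusted p = 2.15e-76, and adjusted p = 0.022 with an estimated correlation). Zbp1, a sensor of unusual nucleic acids, rose by 4.89 ± 0.17 (SE), and Usp18, which restrains interferon signalling, rose by 4.72 ± 0.26. Of 24 chemokines and cytokines, 7 rose (13 adjusted over the list alone), among them Cxcl9, by 5.06 ± 0.35, and Ccl12 (95% interval 3.43 to 4.57). Of 12 complement genes, 7 rose (9 adjusted over the list alone), led by C1ra at 15.9-fold (SE 0.46 on the log2 scale), C1s1 at 13.9-fold (SE 0.54) and C2 at 13.1-fold (SE 0.44). Their changes were smaller on interferon-gamma array 2, where C1ra had a ratio of 2.96, against 4.70 and 4.39 on the other arrays. Among 12 interferon-inducible metabolic enzymes, 3 rose (6 adjusted over the list alone), namely Acod1, which makes itaconate, by 4.21 ± 0.38, Wars by 1.37 ± 0.14 and Ido1, which degrades tryptophan, by 1.25 ± 0.13. The chemokine, complement and enzyme lists passed camera with adjusted p of 2.70e-16, 3.66e-12 and 1.07e-06. None of the 3 passed with an estimated correlation, where the adjusted p was 0.171, 0.162 and 0.129. Their medians were lower on interferon-gamma array 2 (-0.10, 1.16 and 0.18) than on array 1 (0.59, 1.86 and 0.53) and array 3 (0.68, 2.01 and 0.60).

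**Figure D2:**
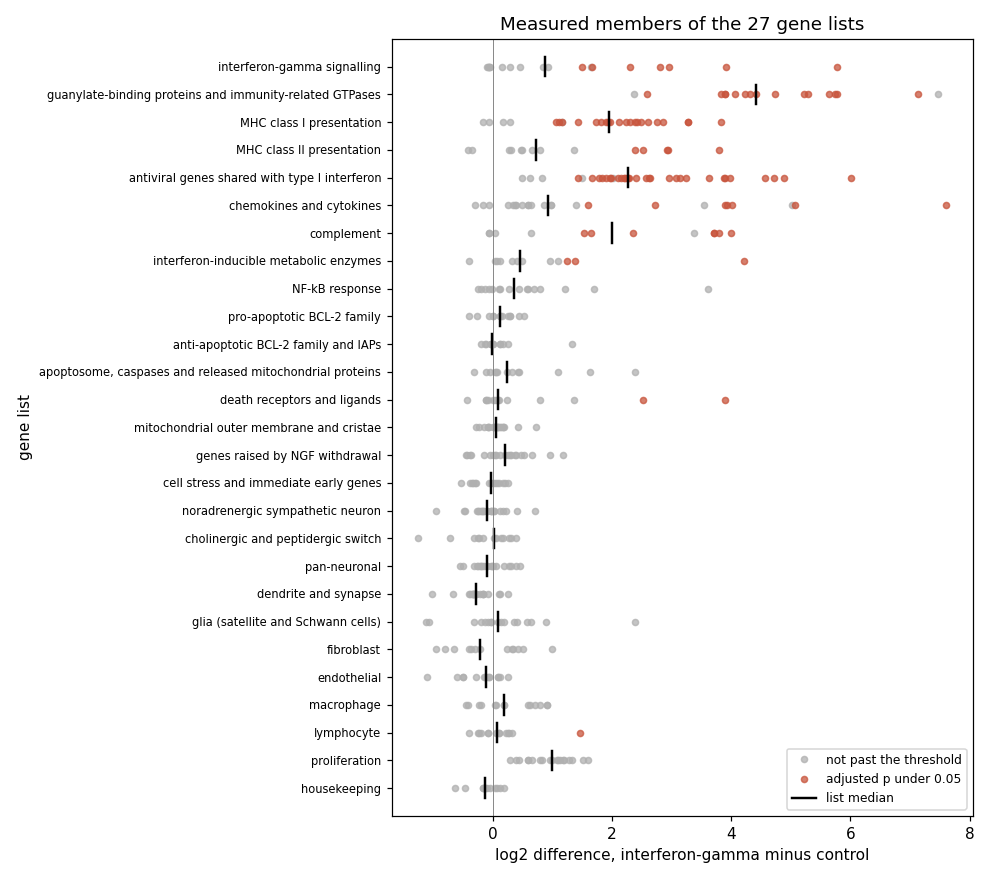
Log2 difference, interferon-gamma minus control (horizontal axis), of each measured member of the 27 gene lists (vertical axis). Points are genes, red where the adjusted p over all genes was under 0.05, and black bars are list medians; the median was 4.42 for the guanylate-binding protein list and -0.01 for the anti-apoptotic list.

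For the mitochondrial route of apoptosis, no gene passed the threshold among 13 pro-apoptotic members of the BCL-2 family, 14 anti-apoptotic members and inhibitors of apoptosis, 20 genes of the mitochondrial outer membrane and cristae, or 13 genes of the apoptosome, the caspases and released mitochondrial proteins. The difference was 0.05 (95% interval -0.36 to 0.46) for Cycs, which encodes cytochrome c, 0.24 (-0.16 to 0.64) for Apaf1, which cytochrome c activates, and -0.13 (-0.60 to 0.34) for Casp9, which Apaf1 recruits. It was -0.00 (-0.48 to 0.47) for Bcl2, -0.12 (-0.45 to 0.21) for Bcl2l1, 0.12 (-0.42 to 0.66) for Bcl2l11 and -0.00 (-0.37 to 0.36) for Xiap. These are means over features that differed. Single features ranged from -0.54 to 0.14 for Bcl2, -0.20 to 0.06 for Bcl2l1, -0.56 to 0.54 for Bcl2l11 and -0.29 to 0.31 for Xiap. The 95% intervals leave room for changes of up to 1.58-fold in Bcl2l11 and 1.56-fold in Apaf1. For some other members the limits lay farther from the control level. The lower limits were 0.412 times the control level for Bok, 0.425 for Pmaip1, 0.524 for Hk2, 0.566 for Bad and 0.584 for Timm23, so a fall of these genes is not excluded either. The upper limits were 2.17-fold for Hrk, 2.25-fold for Bbc3, 2.48-fold for Casp8, 3.47-fold for Pmaip1, 3.57-fold for Casp12, 5.18-fold for Hk2, 7.66-fold for Birc5, 8.67-fold for Casp4 and 11.8-fold for Casp1. Birc5, an inhibitor of apoptosis that dividing cells express, passed without interferon-gamma array 2, at 2.13 (adjusted p = 0.0159), where the 200 genes nearest to it in control mean shifted by a median of 1.37, so much of this value is shared by genes with low control ratios. At an unadjusted p under 0.05 (limma), 1 pro-apoptotic, 0 anti-apoptotic and 1 outer membrane gene were higher and none was lower, and in the caspase list 4 were higher and 1 lower. Adjusted over each list alone, the count was 0 in the first 3 of these lists and 1 in the apoptosome and caspase list.

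The apoptosome and caspase list as a whole lay above other genes by camera (adjusted p = 0.0494), and not with an estimated correlation (adjusted p = 0.554 with an estimated correlation). Its highest values were those of Casp1, at 2.39 ± 0.49 (SE, adjusted p = 0.135), which is known for inflammasomes, Casp4, another inflammatory caspase, at 1.63 ± 0.62, and Casp12, at 1.09 ± 0.31 (adjusted p = 0.370). Without interferon-gamma array 2 the difference of Casp1 was 2.94 and passed the threshold (adjusted p = 0.00405), as it did with array weights (0.0240) and without the genes of low SD (0.00854). In the list of death receptors and ligands, 2 of 14 genes rose, over all genes and adjusted over the list alone. They were Tnfsf10, the death ligand TRAIL, by 3.89 ± 0.34, and Mlkl, the effector of necroptosis, by 2.52 ± 0.32. This list also passed camera narrowly (adjusted p = 0.0494), and not with an estimated correlation (adjusted p = 0.384 with an estimated correlation). The calls of both lists were also lost when control array 1, control array 2 or interferon-gamma array 3 was left out, with adjusted p of 0.0869, 0.165 and 0.184 for the caspase list and 0.129, 0.112 and 0.0749 for the death receptor list. Each was lost without 1 further array, interferon-gamma array 1 for the caspase list (adjusted p = 0.0912) and interferon-gamma array 2 for the death receptor list (adjusted p = 0.0852). With genes on more than 1 list left out, the adjusted p was 0.402 for the death receptor list and 0.0535 for the caspase list, which had 0.0519 with 1 feature per gene. The anti-apoptotic list had a median of -0.01 and a mean of 0.10, and camera gave it an adjusted p of 0.991.

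No member passed the threshold among 16 genes of the NF-kB response, 21 genes known to rise when nerve growth factor is withdrawn, and 15 stress and immediate early genes. The NF-kB list lay above other genes by camera (adjusted p = 0.00215), and not with an estimated correlation (adjusted p = 0.511 with an estimated correlation). The call was also lost without control array 2 (adjusted p = 0.0517) or interferon-gamma array 3 (adjusted p = 0.0629). Its highest member was the adhesion molecule Icam1, at 3.61 ± 0.61 (SE, adjusted p = 0.0663), whose ratio on interferon-gamma array 2 was -0.97, against 1.24 and 1.34 on the other arrays. Icam1 passed without that array, at 4.36 (adjusted p = 0.000701). There the 200 genes nearest to it in control mean shifted by a median of 1.37, and 0.5% of them rose as far. At its control mean of -3.07 these genes are a loose match, and they may understate the shift expected there. Icam1 also passed with quantile normalization (0.0394), array weights (0.0109) and without the genes of low SD (0.00125). Tnfaip2 was at 1.21 ± 0.22 (adjusted p = 0.0880), and passed without that array (0.0194), with array weights (0.0231) and without the genes of high spread (0.0311). Adjusted over the list alone, 3 NF-kB genes passed. Of the withdrawal list, Txnip had a difference of 1.17 ± 0.33 and Jun, a transcription factor of neuronal apoptosis, of 0.96 ± 0.30 (adjusted p = 0.371 and 0.431). Both passed without interferon-gamma array 2, at 1.55 and 1.29, where the 200 genes nearest to each in control mean had median shifts of 1.37 for Txnip and 0.09 for Jun. The withdrawal list had a camera adjusted p of 0.0997, which was 0.0380 without control array 1 and 0.0286 without interferon-gamma array 2, and the stress list, whose lead members were Cdkn1a (-0.54 ± 0.21) and Atf4 (0.25 ± 0.13), of 0.270.

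Genes of neuronal identity did not pass the threshold one by one, in any of the 4 neuronal lists with all 6 arrays. Th, the rate-limiting enzyme of noradrenaline synthesis, differed by -0.20 (95% interval -0.64 to 0.24), and the noradrenergic list of 22 genes had a median of -0.10 (camera, adjusted p = 0.268). Its most extreme members were Npy, a cotransmitter, at -0.97 ± 0.32 (SE) and Chgb, a granule protein, at 0.71 ± 0.21. The pan-neuronal list of 20 genes, including Ina (-0.51 ± 0.22) and Mapt (0.29 ± 0.15), also had a median of -0.10 (camera, adjusted p = 0.20). Without control array 3, both lists lay below other genes by camera, with medians of -0.21 (adjusted p = 0.00576) and -0.19 (adjusted p = 0.0224). The cholinergic and peptidergic list of 13 genes had a median of 0.01 and a mean of -0.13 (adjusted p = 0.333), and held Calcb at -1.26 ± 0.43 and Slc5a7, the choline transporter, at -0.73 ± 0.26. Without interferon-gamma array 2, Slc5a7 was at -1.03 and passed (adjusted p = 0.0195), but the 200 genes nearest to it in control mean also shifted, by a median of -0.63, and 24% of them fell as far. The 19 dendrite and synapse genes were the single list below other genes, with a median of -0.29 (camera, adjusted p = 0.000398), and it did not pass with an estimated correlation (adjusted p = 0.384 with an estimated correlation). Camk2a, a synaptic kinase, differed by -0.68 ± 0.21 and Nlgn1, a synaptic adhesion molecule, by -1.03 ± 0.42, and 0 of the 19 passed adjusted over the list alone. The 2 features of Camk2a differed by -1.33 and -0.02. Nlgn1 had a control mean of 1.93, and all 99 genes above 1.5 shifted by a median of -1.04 on interferon-gamma arrays 1 and 3. The list median on control array 3, -0.136, lay below those on interferon-gamma arrays 2 and 3, -0.025 and -0.042.

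Markers of other cells were examined for shifts that go with the treatment. No gene passed over all genes among 17 glial, 13 fibroblast, 14 endothelial and 14 macrophage markers, and camera gave adjusted p of 0.908, 0.276, 0.0997 and 0.0629. The medians of these lists were 0.08, -0.23, -0.12 and 0.18. Some alternatives moved them past the threshold. With quantile normalization the endothelial median was -0.19 (adjusted p = 0.0404). Without interferon-gamma array 2 the macrophage median was 0.45 (adjusted p = 0.0049) and the glial median 0.33 (adjusted p = 0.0317), and without control array 3 the macrophage median was 0.34 (adjusted p = 0.0224). Without interferon-gamma array 1 the fibroblast and endothelial medians were -0.58 and -0.23 (adjusted p = 0.0169 and 0.0170), and without control array 2 they were -0.50 and -0.20 (adjusted p = 0.0143 and 0.0214). In the macrophage list 3 genes passed adjusted over the list alone, among them Fcer1g, at 0.78 ± 0.14 (SE), and Aif1, at 0.71 ± 0.15. One glial marker passed in that way, Art3, at 2.38 ± 0.47. Over all genes, Art3 passed without interferon-gamma array 2 (2.87, adjusted p = 0.00975), with array weights (adjusted p = 0.0260) and without the genes of low SD (adjusted p = 0.00708). Fcer1g passed without that array (adjusted p = 0.0309), with array weights (adjusted p = 0.0293) and without the genes of high spread (adjusted p = 0.0443), and Aif1 without that array (adjusted p = 0.0480). Other leading members were S100b (-1.07 ± 0.40), Mgp (-0.95 ± 0.41), Pdgfrb (-0.66 ± 0.36), Flt1 (-0.51 ± 0.26) and Emcn (-1.11 ± 0.59). Of 14 lymphocyte genes, Zap70, a kinase of T cells, rose by 1.47 ± 0.22, and the list had a median of 0.07 (adjusted p = 0.720). The housekeeping list had a median of -0.13 (adjusted p = 0.0763), and passed with fry (adjusted p = 0.0488). Its medians were -0.34, -0.20 and -0.29 on the interferon-gamma arrays, below the control values of 0.01, 0.05 and -0.04, with Gapdh at -0.65 ± 0.18 and Tfrc at -0.47 ± 0.18.

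The 19 proliferation genes lay above other genes by camera (median 0.99, adjusted p = 6.71e-07). This call was lost when the very high correlation between these genes, 0.93, was estimated (adjusted p = 0.511 with an estimated correlation), and no member passed, with Top2a at 1.27 ± 0.55 (SE), Bub1 at 1.51 ± 0.70 and Birc5 at 1.33 ± 0.67. The list medians were -0.51 and -0.63 on interferon-gamma arrays 1 and 3, and -2.26 on array 2, within the control values of -2.06, -2.43 and -1.83. Top2a (1.91), Bub1 (2.37) and Birc5 (2.13) passed when interferon-gamma array 2 was left out, where the 200 genes nearest to each in control mean had median shifts of 0.97, 1.37 and 1.37. Control means of -3.25 for Bub1 and -2.44 for Birc5 gave the same median, so the match there is loose. Glial medians were also higher on interferon-gamma arrays 1 and 3, at -0.16 and -0.21, than on array 2, at -1.29. Among the controls, the glial median was likewise lowest on array 2, at -0.925 against -0.374 and -0.519 on arrays 1 and 3. The low glial ratios thus go with the replicate number 2 in both groups.

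The last comparison set the cultured control neurons against the ganglion reference. Proliferation genes had the ratios farthest from 0 among the 8 marker lists compared, with a median of -2.11 ± 0.30 (SD, n = 3) on the log2 scale. Glial markers were at -0.61 ± 0.29 and endothelial markers at -0.59 ± 0.21, below the reference on all 3 arrays. Noradrenergic genes were at 0.08 ± 0.21, and this value depended on single arrays, at 0.04, -0.00 and 0.20 ± 0.06 without control array 1, 2 and 3. Pan-neuronal genes were at 0.21 ± 0.14. Macrophage markers were at -0.23 ± 0.17 and fibroblast markers at -0.07 ± 0.65, with control array 2 at -0.80 against 0.17 and 0.42 on the others (0.30 ± 0.17 without it, -0.19 and -0.31 without control array 1 and 3). Housekeeping genes were at 0.01 ± 0.04. No test was made, since the reference has no replicate of its own and its dye was never swapped, and a ratio near 0 can also come from genes below background in both channels.

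**Figure D3:**
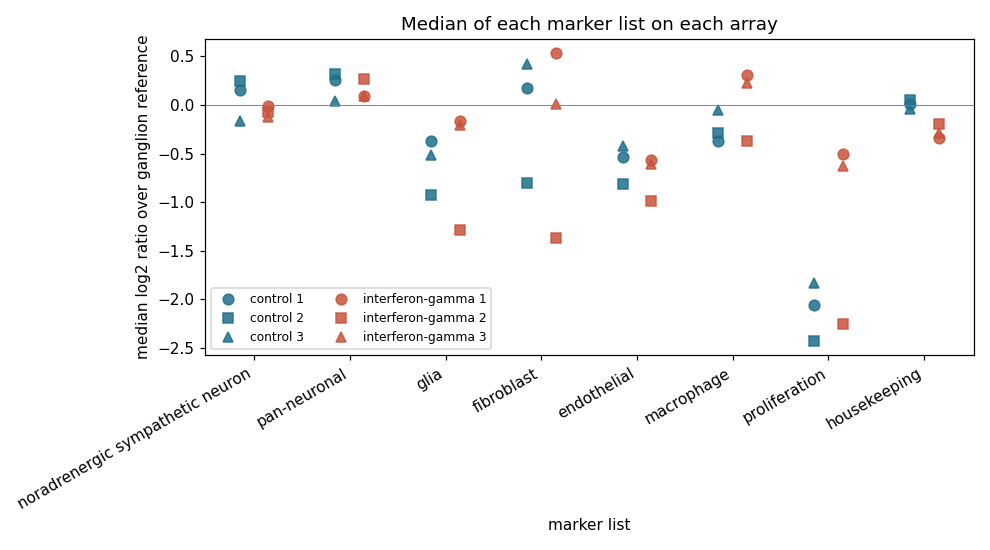
Median log2 ratio over the ganglion reference (vertical axis) of 8 marker lists (horizontal axis) on each of the 6 arrays. Colours are the groups and symbols the replicate numbers; proliferation medians were -1.83 or lower on 4 arrays and -0.51 and -0.63 on interferon-gamma arrays 1 and 3.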

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

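The test of features without a single gene name was chosen after the data were seen. These 11567 features are outside all comparisons above, and 54 of them passed the threshold when all 45220 features were tested for interferon-gamma minus control (limma, adjusted p under 0.05). Of the 54, 53 were higher and 1 lower, and the 53 were at least 2-fold higher than in the control arrays. Feature 38509 rose by 4.99 ± 0.19 (SE, adjusted p = 0.00103) and feature 37458 by 4.77 ± 0.36 (adjusted p = 0.00662), while feature 43181 fell by 1.55 (SE 0.19, adjusted p = 0.0363). Among features with a gene name, 261 passed in the same test.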

How the results depend on the processing

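Treating values of exactly 0 as missing was chosen after the data were seen and gave 216 genes, all among the 217. No named gene reversed under any alternative. Of 36 named genes past the threshold, 23 stayed past it under every alternative that tested them (both filters on spread leave some out), and of 44 not past it, 12 passed under at least 1. Over the arrays left out in turn, 113 to 508 genes passed, 112 to 480 higher and 1 to 28 lower, where fewer arrays alone lower the power. The highest values were without interferon-gamma array 2, and the cause was not tested. The count of lower genes, 4, moved most in proportion. It was 7 with quantile normalization, 7 with 1 feature per gene, 12 without the lower 50% by SD, 14 without the top 10% by spread within groups, 12 with array weights, 10 at an adjusted p under 0.1 and 10 with every feature on its own, and the cause was not tested. The total stayed within 1.5 times under these, at 204 to 288. Among the 27 lists, 13 passed, 10 to 16 with 1 array left out, 10 with fry and 4 with an estimated correlation, which allows for genes that vary together. The 4 lists that passed under every alternative were interferon-gamma signalling, guanylate-binding proteins, MHC class I and the antiviral genes. Macrophage markers against the ganglion moved from -0.23 to -0.44 with 1 feature per gene, and the cause was not tested. Deviations of same-numbered arrays from their group means correlated at 0.06, 0.31 and -0.03, and not every array correlated best with its own number, so the numbers were not taken as pairs. Interferon-gamma array 2 had a higher Pearson's r with control array 2, 0.72, than with interferon-gamma arrays 1 and 3, 0.61 and 0.68. A pairing of the arrays numbered 2 is therefore not excluded. With the replicate number as a block, 166 genes passed, 164 higher and 2 lower, and 156 were among the 217. Of named genes, C1s1, Dkk2, Gbp4, Plec and Tafa2 then did not pass, while Art3 (adjusted p = 0.0153), Icam1 (0.0471), Tnfaip2 (0.0364) and the endothelial list (0.0400) did. As no value was missing, requiring a value on all 6 arrays changed nothing to compare. Signal over background is unknown here, which limits statements on dim genes.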

Other observations

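The tests on control array 3, on the proliferation genes and on myeloid genes were chosen after the results were seen, and so were the genes named in this part. Of the 217 changed genes, 97 were on a list and 120 on none. Outside the lists, Cd274, which encodes the immune checkpoint ligand PD-L1, rose by 2.76, and Lgals9, a galectin, by 2.84. Ifi202b rose by 4.43 and Ifi204 by 4.01, and Gsdmd, the pore-forming effector of pyroptosis, rose by 1.73. Ubd, a ubiquitin-like modifier, rose by 5.27 and Apol6, an apolipoprotein L, by 4.57. Among enzymes, Xdh, the xanthine dehydrogenase, rose by 2.70, Nampt, of NAD synthesis, by 1.51 and Ch25h, which makes 25-hydroxycholesterol, by 1.19.

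In control neurons against the ganglion, the lowest ratios were those of Cxcl10 (-6.31 ± 0.92, SD, n = 3), Cxcl2 (-5.68 ± 0.16), Cxcl1 (-4.39 ± 0.34) and the neuropeptide gene Nts (-3.92 ± 0.48), and Penk, the enkephalin precursor, was at -3.66 ± 0.37. The 10 lowest also held Pbk, a kinase of dividing cells (-3.47 ± 0.25), and Cyp1a1 (-3.45 ± 0.31). With interferon-gamma, Cxcl10 reached 1.29 ± 1.62, while Cxcl2 stood at -5.29 ± 0.96 and Nts at -4.16 ± 0.74. The highest were Ctla2a and Ctla2b, homologues of a protease propeptide, at 3.93 ± 0.14 and 3.92 ± 0.16.

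Control array 3 held higher ratios of some interferon-inducible genes than control arrays 1 and 2. Iigp1 was at 6.10, against 0.78 and 1.84, and 9 of the 213 risen genes (4.23%) exceeded both other controls by over 1 on the log2 scale, against 1 gene on control array 1 and 0 on array 2, while 1.77% of all other genes did so on array 3. Carry-over of treated RNA was not settled. Iigp1 and the 9 genes would need shares from 0.707% to 18.9%. At their median of 5.06%, the 62 genes risen 8-fold or more differed from the prediction by a median of -0.61. The median difference in size between control arrays 1 and 2 was 0.25. Batf2, for example, was at 0.08 where 2.02 was predicted. But this share came from genes picked for high ratios on control array 3, so it tends to overpredict other genes, whatever the cause. No share was fitted to all risen genes. More cells of another type remain open, since the largest excess of a marker list on this array was 0.25, for fibroblasts, and a low interferon exposure of that culture was not tested.

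The proliferation genes on interferon-gamma arrays 1 and 3 lay 1.61 above the control mean, and 3 explanations were tested. Ratios drawn towards 0 on both arrays may account for most of it, since 10000 random lists of genes not past the threshold, matched on the control mean, shifted by a median of 1.201, with the proliferation list at percentile 99.6, and all 99 genes with control ratios above 1.5 shifted by a median of -1.04, while on array 2 the matched lists shifted by -0.20 and the 99 genes by 0.05. What keeps this open is that genes with such low ratios include other cell cycle genes, such as Pbk. The random lists drew genes independently, while the proliferation genes vary together (correlation 0.93), so the percentile may overstate the excess of the list. Matched genes also lay up to 0.87 away in control mean. More dividing non-neuronal cells could also add to the rise, since on average glial medians were 0.42 and fibroblast medians 0.34 above the control mean. Control array 2 lowered that mean, however. Its fibroblast median was -0.80, against 0.17 and 0.42 on control arrays 1 and 3, and its glial median -0.925, against -0.374 and -0.519. Without control array 2, little of the fibroblast difference remains. But fibroblast markers on array 3 were below control arrays 1 and 3. A rise on every treated array was not seen. Of the 3 treated arrays, 2 lay above all controls, and array 2 lay at -0.15 from the control mean. As array 2 is a single array, whether interferon-gamma raises these genes stays open.

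Some risen genes are known from myeloid cells, and of 28 such genes listed after the values were seen, 27 were measured and 14 rose. The median was 1.01 over all 27 and 1.87 over the 14 that rose, and Clec4d (-0.63) and Fcgr2b (-0.40) lay below 0. The risen genes included the Fc receptor Fcgr1 (3.07 ± 0.22, SE), Cd52 (2.43 ± 0.14), Fpr2 (2.04 ± 0.23) and Clec7a (1.93 ± 0.28). More macrophages in the treated cultures could account for part of this and were not excluded: the 14 macrophage markers fixed in advance had a mean shift of 0.26 with an upper 95% bound over genes of 0.54, which is above the lower quartile of the 27 genes, 0.48, and their median was 0.45 without interferon-gamma array 2. Whether the rise took place in neurons or in other cells of the cultures was not tested.

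For the 217 genes changed by interferon-gamma, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many genes, and the highest of the others gave 6. With 10 splits a share under 0.05 cannot be reached.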
